A study of Homo sapiens with 16 samples.

How the data were processed

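RNA from A549 cells, a human lung adenocarcinoma line, was measured on 16 one-colour Agilent gene expression arrays. Per the labels, the cells were left untreated (0 h) or received DMSO, the solvent control, or 1 of 4 compounds described as allosteric inhibitors of atypical protein kinase C and named only by code (PS432, PSX706, PSX626 and PSX146). Medium and cells were harvested together, and 100 ng of total RNA was labelled with Cy3. Doses are printed in mM because the labels write that unit, and the files hold nothing against which the unit could be checked. Every condition had 1 array, numbered as replicate 1. Arrays were matched only by time or dose, used as blocks, because no label links an array to another one by dish or passage. Nothing states that arrays came from separate cultures, so p-values measure the spread between arrays.

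The scanner files hold spot intensity as deposited, quantified by the authors' facility with Agilent Feature Extraction 10.7.3.1 per the file headers. That processed signal is background-subtracted and spatially detrended within each array and is not scaled between arrays. The raw mean spot signal and the raw median local background are intensity values of the same deposited files. A further deposited file of the authors holds log2 values of 1407 entries for 1405 probes on 9 arrays (untreated, PS432 25 mM and DMSO at each time), with a probe selection and normalization that the file does not state. Its columns headed P2 and D were read as PS432 25 mM and DMSO. All of its array columns were used (0 not used), only as an alternative source of values. Across its 1405 probes the PS432 minus DMSO differences in that file and in the scanner files had Pearson r of 0.908, 0.960, 0.972 and 0.975 at 4, 8, 24 and 48 h; probes are not independent replicates.

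Each array held 62976 spots, of which 58717 were not controls, for 42405 distinct probes. Spots flagged as outliers (244 to 440 per array) were set missing, spots of a probe were averaged, and 19 probes left without a value on an array were dropped. Probes had to be well above background on at least 2 of the 16 arrays, which 28546 did. Gene names came from the files' accessions and symbols through the supplied RefSeq table (assembly GRCh38.p14, used for names only), which gave a current symbol to 28406 probes (25715 by accession, 2179 by symbol, 512 by an older symbol) and none to 13999. The latter kept the name in the file, and 1817 probes had no name at all. One probe per gene, the one with the highest mean, left 21561 genes, 15653 of them with a current symbol. Probe coordinates are hg19 as the files give them. A genome or transcript annotation of that build was not used here, so exons and untranslated regions are not given.

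Values were log2 of the processed signal minus each array's 75th percentile. That percentile lay between 627 and 1081 intensity units, the median signal between 53.9 and 83.3, and the local background between 15 and 21. Between 24457 and 27300 probes per array (57.7% to 64.4%) were well above background, and 0 were saturated. The number of arrays limits the precision. The arrays lay on 2 slides: untreated, the 4 PS432 25 mM arrays and DMSO at 4, 8 and 24 h on slide 1, and DMSO at 48 h, PS432 10 and 50 mM and all other compounds on slide 2.

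Gene-wise linear models were fitted with limma 3.58.1 (lmFit, eBayes with an intensity trend, two-sided) in R 4.3.3 with jsonlite 2.0.0 and the package data.table (1.17.8), and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 21561 genes. The comparisons, gene lists and rule for naming genes were fixed before the data were examined. PS432 25 mM was compared with DMSO over the 4 times with time as a block, and the change of that difference per doubling of time was tested in the same 8 arrays. Culture time was tested over the untreated and DMSO arrays (5) on log2 of hours plus 1. PS432 dose was tested as a straight line over the DMSO, 10, 25 and 50 mM arrays at 24 h, per 10 mM. PSX706, PSX626, PSX146 and PS432 were each compared with DMSO in a fit of all 16 arrays with time as a factor. That fit assumes 1 PS432 effect for all its doses and times. Its DMSO level at 24 h therefore rests also on the PS432 arrays. Where the PS432 effect changes with time or dose, a compound's value in it can differ from the difference to the DMSO array. PSX706, PSX626 and PS432 were compared with each other at 25 and 50 mM and 24 h in 6 arrays with dose as a block, without DMSO. With 1 array per dose or time, the spread in these fits is the variation over times or doses that the model leaves. Pairs of single arrays were described by counts of genes detected on both and differing by at least 2-fold, with no test, and by the percentile of a list's median among 10000 random lists of the same size and expression.

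A set of 31 gene lists was fixed: aPKC and polarity complex, PKC-iota linked cancer genes, NF-kappaB targets, DNA replication, mitosis, p53 targets, BCL2 family, ATF4 and amino acid response, unfolded protein response, heat shock, NRF2 targets, AhR targets, metallothioneins, cholesterol synthesis and uptake, fatty acid synthesis, hypoxia, glycolysis, YAP/TAZ targets, ERK pathway output, immediate early genes, mesenchymal and TGF-beta genes, epithelial junction and keratin genes, interferon-stimulated genes, lysosome and autophagy, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, alveolar and airway markers, and markers of fibroblasts, leukocytes and endothelium. Lists with at least 5 measured genes (29) were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. A limma test of each list's mean was added after the data were seen. Named genes were PRKCI and PRKCZ, the largest called rises and falls with a gene symbol (10 of each, changed the same way at all 4 times, for PS432 over 4 times; 5 of each for the other comparisons), and up to 4 (or 3) called members of lists that passed. Where no gene was called, the 3 genes with the lowest p in each direction were named, and any further list member was chosen after its values were seen. For pairs of single arrays the 5 largest differences each way were named. A gene not well above background on any array of an arm is given as a bound, "at least" the stated fold.

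The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among 21561. The noise came from each comparison's moderated gene variances of eBayes, which differ less between genes than the raw ones. The shares called below may therefore not hold for the real arrays, and a comparison with 0 calls can still hold 4-fold changes. Of the 2-fold and 4-fold changes it called 57% and 87% for PS432 25 mM over 4 times, 24% and 75% for its time trend, 24% and 69% for culture time, 24% and 76% for PS432 dose, 24% and 72% for PSX706, 28% and 81% for PSX626, 8% and 68% for PSX146, and 62% and 90% for PS432 over all doses. At matched doses it called 37% and 80% for PSX706 against PS432, 37% and 78% for PSX626 against PS432, and 33% and 74% for PSX626 against PSX706. Every called change had the right sign. Calls among unchanged genes numbered between 1 and 21. They were 14 beside 99 changed genes called for the time trend, 18 beside 100 for dose and 21 beside 117 for PSX706 against PS432. For PSX626 they were 9 beside 115 against PS432 and 13 beside 107 against PSX706. In these fits the false share exceeded the 0.05 threshold, so the adjusted p may not hold its level there. Culture time and PS432 against DMSO exceeded it too. It was not exceeded for PSX626 (5 beside 109), PSX146 (4 beside 76) and PSX706 (1 beside 96) against DMSO. Both of 2 lists shifted by simulation were found in each comparison, and 1 of 27 unshifted lists was called in the time trend and 0 in the others. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera calls a list falsely where its members vary together.

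Alternatives tried were normexp background correction (offset 50) with quantile normalization, quantile scaling, no filter on dim probes (31350 genes), detection on all 16 arrays (16914 genes), the mean of a gene's probes, eBayes without the intensity trend, the authors' table, slide as a covariate or arrays of 1 slide, log dose, no time block, DMSO arrays only, arrays at 24 h only, compound differences in the 16-array fit, other fold thresholds, and leaving out each array or time. A fit with each array's log2 75th percentile as a covariate, and list tests under quantile scaling or without the 4 h arrays, were added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.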

Results

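Gene expression was measured on 16 arrays, with 1 array per condition and no replicates: untreated A549 cells at 0 h, DMSO at 4, 8, 24 and 48 h, PS432 at 25 mM (the unit as labelled) at the same 4 times, and at 24 h PS432 at 10 and 50 mM, PSX706 and PSX626 at 25 and 50 mM, and PSX146 at 25 mM. The arrays detected between 24457 and 27300 probes well above background, and their number limits the precision of every value. The design asks how expression in these lung cancer cells changes after compounds aimed at the atypical protein kinase C enzymes PKC-iota and PKC-zeta, and whether the compounds differ. Values are log2 differences with the standard error (SE) of the limma fit, and n counts arrays.

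The first comparison set PS432 at 25 mM against DMSO over the 4 times (n = 4 arrays each). The chemokine genes CXCL1, CXCL2 and CXCL3, whose products attract neutrophils, differed by 1.35 ± 0.11, 2.11 ± 0.17 and 1.74 ± 0.16 and were higher than with DMSO at 4 of 4 times. On the untreated array at 0 h they stood at 1.57, 2.02 and -1.15. At 4 h they were 1.57, 2.38 and -0.80 with PS432 and 0.24, 0.64 and -2.42 with DMSO, so much of the early difference was DMSO below untreated. The genes of the kinases themselves were 0.01 ± 0.10 for PRKCI (95% interval -0.24 to 0.25) and 0.07 ± 0.11 for PRKCZ (-0.18 to 0.33). Their probes were A_33_P3294578 on hg19 chromosome 3, 170023598 to 170023657, and A_23_P51187 on chromosome 1, 2116703 to 2116762. MARCKSL1, which codes for an actin-binding substrate of protein kinase C, was -0.79 ± 0.12. HSPA1B, an inducible HSP70 chaperone gene, was -1.27 ± 0.20, and CHKA, the gene of choline kinase, -0.75 ± 0.12. No single gene passed, since limma called 0 of 21561 (3687 at an unadjusted p under 0.05, with 1078 expected by chance). The lowest adjusted p was 0.096, for CXCL1 and CXCL2.

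As groups, NF-kappaB targets and genes of the ATF4 and amino acid response were higher with PS432, and cell division genes were lower. NF-kappaB targets had a median of 1.18 with 21 of 22 members positive and 19 called when adjusted over the list alone (camera adjusted p = 6.15e-16, and adjusted p = 0.518 with an estimated correlation). The ATF4 list, which holds genes switched on when amino acids run short, had a median of 0.85 and 20 of 25 members called adjusted over the list alone (camera adjusted p = 1.71e-13, and adjusted p = 0.518 with an estimated correlation). Its members DDIT3 and ATF3, stress-induced transcription factors, were 2.04 ± 0.25 and 1.96 ± 0.25, each with an adjusted p of 0.158. All 29 DNA replication genes and all 25 mitosis genes were negative, with medians of -0.81 and -0.75. Of these, 15 and 21 were called adjusted over the list alone (camera adjusted p = 7.74e-14 and 2.58e-14, and adjusted p = 0.518 with an estimated correlation for both). Heat shock genes had a median of -0.35 (4 of 20 adjusted over the list alone), with HSPA1A at -1.60 ± 0.27. Immediate early genes, which respond first to growth signals and stress, had a median of 0.75 (11 of 14 adjusted over the list alone), and EGR1 was 1.14 ± 0.14. For these 2 lists camera's adjusted p was 8.12e-08 and 2.07e-08, and adjusted p = 0.518 with an estimated correlation for both.

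Among the other lists higher with PS432 were p53 targets (median 0.46, with GDF15 at 1.12 ± 0.11), the BCL2 family of cell death regulators (0.27, with PMAIP1 at 1.16 ± 0.14), YAP/TAZ targets (0.48, with CCN1 at 1.27 ± 0.29), ERK pathway output (0.37, with DUSP6 at 0.94 ± 0.14), mesenchymal genes (0.26) and cytosolic ribosomal proteins (0.13). By contrast NRF2 targets (-0.25), cholesterol genes (-0.23) and glycolysis genes (-0.12) were lower, although HK2, a hexokinase gene of the glycolysis list, was 1.45 ± 0.42. Adjusted over the list alone, 5 p53 targets, 5 YAP/TAZ targets, 6 ERK genes and 5 BCL2 family genes were higher and 1 BCL2 family gene lower, against 0 in the other 5 of these lists. Across the 29 lists tested, 15 passed camera and 0 passed with an estimated correlation (lowest adjusted p = 0.518 with an estimated correlation). Limma on the list means called NF-kappaB, ATF4, heat shock and immediate early genes. The aPKC and polarity list had a median of 0.01 (camera adjusted p = 0.671) and genes linked to PKC-iota in cancer -0.09 (0.632). Without the 48 h arrays, which lay on different slides, 6 genes were called, in a fit of all 16 arrays with slide as a covariate 30, and with array signal as a covariate, an alternative added after the data were seen, 605.

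The second comparison tested whether the PS432 effect grew with time, and 3107 genes changed per doubling of time (1258 rose, 1849 fell; limma, n = 8 arrays). A rise or fall here is that of the PS432 minus DMSO difference, to which both arms contribute. E2F1, which drives entry into S phase, fell by 0.85 ± 0.13 on the log2 scale per doubling (adjusted p = 0.00636), and the proliferation marker MKI67 fell by 0.67 ± 0.07 (0.00279). CDKN1A, the p53 target that codes for the cell cycle inhibitor p21, rose by 0.83 ± 0.08 (0.0024). At 48 h LAMP3, a lysosomal membrane protein gene, differed from DMSO by 5.37, and its trend was 1.60 ± 0.13 (0.00179).

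DNA replication genes fell in 24 of 29 cases (28 adjusted over the list alone), among them CCNE2 and CDT1. Mitosis genes fell in 18 of 25 (24 adjusted over the list alone), among them CENPF and KIF11. Camera's adjusted p was 8.52e-14 and 1.76e-10, and adjusted p = 0.588 and 0.594 with an estimated correlation. Of the p53 targets 15 of 22 rose (17 adjusted over the list alone), including SESN1 at 0.70 ± 0.11 and BTG2 at 0.65 ± 0.09 (camera adjusted p = 1.84e-12, and adjusted p = 0.585 with an estimated correlation). NF-kappaB targets rose in 10 of 22 cases and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 1.05e-05, and adjusted p = 0.588 with an estimated correlation). The difference in RELB, a subunit of that factor, rose by 0.78 ± 0.08, with levels from 4.37 at 4 h to 4.97 at 48 h with PS432 and from 4.09 to 1.84 with DMSO. That in PTGS2, the inducible cyclooxygenase gene, fell by 0.79 ± 0.11, with levels from -1.29 to -1.07 with PS432 and from -1.77 to 1.33 with DMSO. The cytokine gene IL6 was at least 24.2-fold higher with PS432 at 48 h. ERK pathway genes rose in 5 of 14 cases and fell in 1 (the same adjusted over the list alone; camera adjusted p = 0.000236, and adjusted p = 0.585 with an estimated correlation). The difference in DUSP5, a phosphatase gene, rose by 0.87 ± 0.07. That in FOSL1, a transcription factor gene, rose by 0.88 ± 0.08, with levels of 0.55 and 0.63 at 4 and 48 h with PS432 and a decline from 0.53 to -2.46 with DMSO.

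Immediate early genes went both ways, with the difference in JUN up by 0.71 ± 0.07 and that in FOS at -0.64 ± 0.10 (5 of 14 rose and 1 fell, the same adjusted over the list alone; camera adjusted p = 0.000708, and adjusted p = 0.585 with an estimated correlation). YAP/TAZ targets rose in 9 of 20 cases (10 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.000236, and adjusted p = 0.585 with an estimated correlation). The difference in the receptor gene AXL rose by 0.69 ± 0.10, from levels of 3.50 to 4.49 with PS432 and 3.69 to 2.07 with DMSO. JUN went from 1.01 to 1.32 with PS432 and from 0.39 to -1.72 with DMSO. BCL2 family genes rose in 5 of 15 cases (5 adjusted over the list alone; camera adjusted p = 0.00213, and adjusted p = 0.585 with an estimated correlation). They included the survival genes BCL2L1 and MCL1. Mesenchymal genes rose in 3 of 15 and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00282, and adjusted p = 0.588 with an estimated correlation). In that list the difference in FN1, the fibronectin gene, fell by 0.87 ± 0.11, with levels from -3.59 to -4.41 with PS432 and from -4.54 to -2.13 with DMSO. Cholesterol genes fell in 7 of 25 cases (7 adjusted over the list alone; camera adjusted p = 0.00309, and adjusted p = 0.798 with an estimated correlation). Ribosomal protein genes rose in 2 of 22 cases (1 adjusted over the list alone; camera adjusted p = 0.00213) and ribosome biogenesis genes in 0 of 17 (camera adjusted p = 0.0249), with adjusted p = 0.696 and 0.588 with an estimated correlation.

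Among the largest changes, at 48 h the keratin gene KRT34 was at least 68-fold higher with PS432 than with DMSO, the chemokine gene CXCL10 at least 13.4-fold and FOXB2 at least 9.49-fold. TMCO2, LGALS2, SPON2, SLC26A9 and KCNJ15 were at least 158, 96.1, 70.2, 44.7 and 39.9-fold lower. For TMCO2 and KCNJ15 the fold rested on the DMSO array at 48 h, at -0.04 and -2.02, with the highest of the other DMSO arrays at -6.82 and -7.54. CXCL10 and FOXB2 were -3.17 and -3.67 with PS432 at 48 h but also -4.18 and -4.64 with DMSO at 4 h. CDH8, which also passed, was below background in both arms at 48 h. The PS432 array at 4 h was dimmer than its DMSO array (log2 of the 75th percentile, PS432 minus DMSO, -0.72), and genes higher on the dimmer array of both PSX706 and PSX626 made up 24.4% of the falls against 10.6% of all genes. The calls depended on the late times and on the variance prior: 1261 genes were called without 48 h, 1643 without 24 h, 2521 without 4 h, 710 with array signal as a covariate and 0 without the intensity trend in eBayes (5791 at an unadjusted p under 0.05).

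At single times, the ATF4 list was already higher with PS432 at 4 h (median 0.53) and stood at 1.17, 1.45 and 0.51 at 8, 24 and 48 h, at or above percentile 99.9 of 10000 random lists each time. At 8 h the largest differences included CHAC1 at 2.61, DDIT3 at 2.51 and STC2 at 2.49, all members of that list. NF-kappaB targets had medians of 0.67, 0.50, 1.39 and 1.48 (percentile 100 each time). DNA replication genes had medians of -0.22, -0.26, -0.94 and -2.00 (percentiles 0.4, 0, 0 and 0), and p53 targets -0.13, 0.07, 0.56 and 1.24. PS432 and DMSO differed by at least 2-fold in 1093 genes at 4 h (1013 higher, 80 lower), 186 at 8 h, 1264 at 24 h and 2723 at 48 h, with no replicate check. At 4 h, where the PS432 array was the dimmer one, most differences lay in 1 direction. DMSO arrays of neighbouring times differed in 141 genes (8 against 4 h), 515 (24 against 8 h) and 890 (48 against 24 h).

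**Figure D1:**
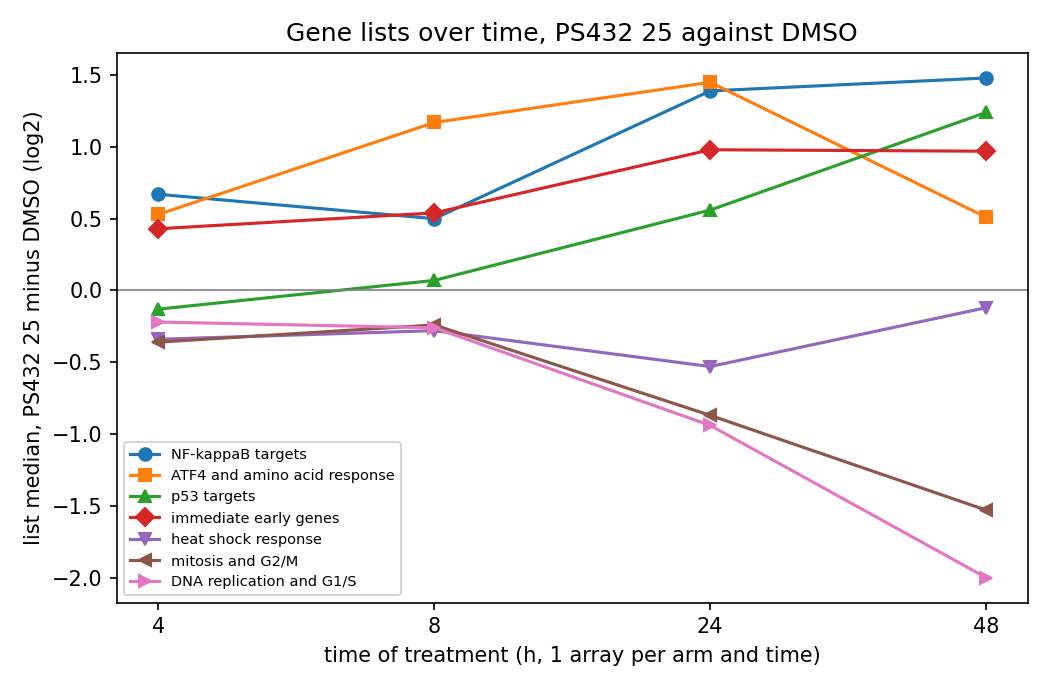
Median log2 difference between PS432 25 mM and DMSO for gene lists at 4, 8, 24 and 48 h, with 1 array per arm and time. NF-kappaB targets lie between 0.50 and 1.48 and DNA replication genes between -2.00 and -0.22.

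Culture time without compound was examined over the untreated and DMSO arrays (n = 5), as the background to the changes with PS432. NF-kappaB targets, YAP/TAZ targets and immediate early genes were lower at later times, by medians of -0.14, -0.17 and -0.14 per unit of log2 time. The members BIRC3, an inhibitor of apoptosis, CCN1, a secreted matrix protein, and EGR1 were -0.33 ± 0.04, -0.38 ± 0.06 and -0.47 ± 0.06. ID4, which codes for an inhibitor of differentiation factors, was 0.69 ± 0.08 (adjusted p = 0.215) and at 48 h at least 15.9-fold higher than in the untreated array. SPNS2, a lipid transporter gene, was -0.42 ± 0.04 (0.215). Adjusted over the list alone, 11 of 22 NF-kappaB targets, 12 of 20 YAP/TAZ targets and 7 of 14 immediate early genes passed (camera adjusted p = 7.32e-11, 3.61e-10 and 3.87e-07, and adjusted p = 0.137, 0.255 and 0.255 with an estimated correlation).

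Genes for DNA replication (-0.11), mitosis (-0.09), heat shock (-0.12), ribosome biogenesis (-0.10), p53 targets (-0.05) and mesenchymal genes (-0.09) were also lower with time by camera, each with adjusted p = 0.520 with an estimated correlation. Genes of the ATF4 list (0.14), NRF2 targets (0.05), interferon-stimulated genes (0.08) and alveolar markers (0.09) were higher, with adjusted p = 0.603, 0.520, 0.520 and 0.520 with an estimated correlation. Each of these 10 lists had 0 members adjusted over the list alone. From 24 to 48 h in DMSO, TXNIP, a gene induced by glucose, was higher by 4.01 and the ATF4 list by a median of 1.08 (percentile 100), with no replicate check and the arrays on different slides. Of the 29 lists 13 passed camera, 3 passed limma on the list means and 0 passed with an estimated correlation (lowest adjusted p = 0.137 with an estimated correlation). No gene passed (limma, 0 called, 3087 at an unadjusted p under 0.05), whereas the 4 DMSO arrays without the untreated one called 649.

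The dose comparison asked which genes followed PS432 dose at 24 h over DMSO, 10, 25 and 50 mM, and 2221 genes did (1111 rose, 1110 fell; limma, n = 4 arrays). NIBAN1, a gene induced by cell stress, rose by 1.20 ± 0.19 per 10 mM (adjusted p = 0.0239), and the glycolytic gene HK2 by 0.88 ± 0.09 (0.0104). CLDN2, a claudin of tight junctions, fell by 1.34 ± 0.13 (0.0103), and BCAS1 fell by 1.15 ± 0.15 (0.0177). The slopes do not mean a graded change from the lowest dose. Against DMSO at 10, 25 and 50 mM, CLDN2 stood at 0.29, -2.67 and -6.17 and BCAS1 at 0.74, -2.02 and -5.11. HK2 stood at -0.05, 2.03 and 4.06, whereas NIBAN1 was already higher at 10 mM (2.24, 5.18 and 6.12). At 50 mM the collagenase gene MMP1 was at least 41.5-fold, PTX3 at least 31.9-fold, HCAR3 at least 18.6-fold and OLAH at least 17.9-fold higher than in DMSO. LGALS2, MRAP2 and PACSIN1 were at least 45.2, 21.1 and 18-fold lower.

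DNA replication genes fell in 27 of 29 cases (29 adjusted over the list alone; camera adjusted p = 3.25e-26, and adjusted p = 0.568 with an estimated correlation). E2F1 was -0.65 ± 0.04 and MCM10, a replication initiation gene, -0.64 ± 0.04 per 10 mM. Mitosis genes fell in 18 of 25 (22 adjusted over the list alone; camera adjusted p = 2.26e-15, and adjusted p = 0.568 with an estimated correlation). CDK1, the mitotic kinase gene, was -0.42 ± 0.03. NF-kappaB targets rose in 14 of 22 (18 adjusted over the list alone; camera adjusted p = 1.46e-10, and adjusted p = 0.568 with an estimated correlation). Among them TRAF1 rose by 0.95 ± 0.15, and at 50 mM IL6 was at least 21.6-fold and the chemokine gene CCL20 at least 20.6-fold higher. Unfolded protein response genes rose in 7 of 19 (15 adjusted over the list alone; camera adjusted p = 2.26e-08, and adjusted p = 0.625 with an estimated correlation). HSPA5, the gene of the endoplasmic reticulum chaperone BiP, rose by 0.78 ± 0.09 and HERPUD1 by 0.58 ± 0.05. That list's median against DMSO was 0.00, 0.04 and 1.38 at 10, 25 and 50 mM. ATF4 genes rose in 6 of 25 (13 adjusted over the list alone; camera adjusted p = 3.83e-06, and adjusted p = 0.644 with an estimated correlation). ATF3 rose by 0.80 ± 0.07 and DDIT3 by 0.77 ± 0.08.

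p53 targets rose in 10 of 22 (15 adjusted over the list alone), immediate early genes in 7 of 14 (10 alone), ERK pathway genes in 6 of 14 (7 up and 1 down alone) and BCL2 family genes in 4 of 15 (8 alone). CDKN1A rose by 0.43 ± 0.06 and the p53-induced death gene BBC3 by 0.39 ± 0.07. Camera's adjusted p for these 4 lists was 9.72e-07, 7.51e-06, 0.00501 and 0.0159, and adjusted p = 0.568, 0.568, 0.625 and 0.642 with an estimated correlation. NRF2 targets fell in 6 of 23 (7 down and 1 up adjusted over the list alone), glycolysis genes fell in 4 of 17 with HK2 the 1 that rose (the same adjusted over the list alone), and heat shock genes fell in 2 of 20 (4 adjusted over the list alone). Oxidative phosphorylation genes of the nucleus fell in 2 of 23 (2 adjusted over the list alone) and the cholesterol gene ACAT2 fell as 1 of 25 (0 adjusted over the list alone). Camera's adjusted p for these 5 lists lay between 0.000283 and 0.0407, and that for ribosomal proteins and YAP/TAZ targets, with 0 members called, was 0.00134 and 0.0394. None of the 16 lists that passed camera did with an estimated correlation, for which the lowest was adjusted p = 0.568 with an estimated correlation. The dose calls fell to 0 without the DMSO array, with log dose, with array signal as a covariate or without the intensity trend (5591 at an unadjusted p under 0.05), and to 2 without the 50 mM array. With slide as a covariate in the 16-array fit 5497 genes were called, 2045 of them shared.

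Over all its doses and times PS432 (n = 6 arrays, in the fit of all 16) differed from DMSO past the threshold in 1 gene. GDF15, a secreted stress cytokine and p53 target, was higher by 1.14 ± 0.11 (95% interval 0.90 to 1.38, limma adjusted p = 0.0127). Its level was 4.88 untreated, 4.65, 4.98, 5.70 and 6.78 with PS432 25 mM at 4, 8, 24 and 48 h, and 3.74, 3.98, 4.46 and 5.45 with DMSO. The early difference thus lay in DMSO being below the untreated array. Its probe was A_23_P16523 on hg19 chromosome 19, 18499890 to 18499949. DDIT4, an inhibitor of mTOR signalling induced by stress, was 1.16 ± 0.16 (0.0639) and CXCL2 2.14 ± 0.40 (0.164). ATF4 genes had a median of 0.83 (19 of 25 adjusted over the list alone), NF-kappaB targets 1.07 (16 of 22), mitosis genes -0.75 (25 of 25), replication genes -0.84 (26 of 29) and heat shock genes -0.35 (12 of 20). Camera's adjusted p for these 5 lists was 4.85e-14, 2.43e-11, 3.65e-16, 4.17e-14 and 9.86e-10, and adjusted p = 0.379, 0.436, 0.436, 0.436 and 0.379 with an estimated correlation. Immediate early genes (0.77), p53 targets (0.47), the BCL2 family (0.23), YAP/TAZ targets (0.42), ERK output (0.37), mesenchymal genes (0.24) and ribosomal proteins (0.12) were also higher by camera, and NRF2 targets (-0.24), glycolysis (-0.15) and oxidative phosphorylation genes (-0.07) lower. Adjusted over the list alone these had 7 immediate early, 5 p53, 5 BCL2 family and 3 ERK members higher and 0 in the others, with the lowest adjusted p = 0.379 with an estimated correlation. The single call was lost in the 24 h arrays alone, without the intensity trend, without either array at 8 h, or without PS432 25 mM or DMSO at 24 h. It became 727 calls without the 10 mM array, 9 without either 48 h array, and 12 with array signal as a covariate.

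PSX706 was compared with DMSO to see what a related compound does alone (n = 2 arrays, in the fit of all 16). OASL, an interferon-induced antiviral gene, was the 1 gene called and rose by 2.45 ± 0.26 (95% interval 1.88 to 3.02, limma adjusted p = 0.0377). Its probe was A_23_P139786 on hg19 chromosome 12, 121458320 to 121458379. Interferon-stimulated genes as a list had a median of 0.46 with 18 of 22 positive. Over all genes 1 member was called and 6 adjusted over the list alone (camera adjusted p = 9.19e-10, and adjusted p = 0.0593 with an estimated correlation). ATF4 genes had a median of 1.05 (16 of 25 adjusted over the list alone; camera adjusted p = 1.07e-19, and adjusted p = 0.255 with an estimated correlation). ASNS, the asparagine synthetase gene, was 1.26 ± 0.26 and the secreted hormone gene STC2 2.36 ± 0.52. Against the DMSO array at 24 h alone ASNS stood at 1.43 and 1.57 with 25 and 50 mM, as the DMSO level of the fit rests also on the PS432 arrays. NF-kappaB targets had a median of 1.04 (4 of 22 adjusted over the list alone; camera adjusted p = 7.2e-12, and adjusted p = 0.374 with an estimated correlation). CXCL2 was 2.43 ± 0.60. All 25 cholesterol genes were negative, with a median of -0.51 (0 adjusted over the list alone; camera adjusted p = 5.36e-09, and adjusted p = 0.374 with an estimated correlation), and DHCR7 was -0.85 ± 0.36.

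Mitosis and DNA replication genes had medians of -0.52 and -0.48 (1 and 0 adjusted over the list alone; camera adjusted p = 1.99e-08 and 0.000205, and adjusted p = 0.515 and 0.586 with an estimated correlation). Immediate early genes (0.64), YAP/TAZ targets (0.39) and mesenchymal genes (0.33) were higher by camera, and AhR targets (-0.45), metallothioneins (-0.34), glycolysis (-0.26), fatty acid synthesis (-0.18) and oxidative phosphorylation genes (-0.11) lower. All of these had 0 members adjusted over the list alone and between adjusted p = 0.374 and 0.586 with an estimated correlation. At both doses NIBAN1 differed from DMSO by 3.93 and 4.59 and BEX2 by 3.25 and 3.65. Likewise AXIN2 and RNF43, negative regulators of Wnt signalling, differed by -2.79 and -3.39 and by -2.31 and -2.70. Of the genes detected on the 3 arrays, 191 were 2-fold higher and 160 lower at both doses, with no replicate check and 1 DMSO array shared by both doses. At an unadjusted p under 0.05 there were 1224 genes. The OASL call was lost in the 24 h arrays alone, without the filter on dim probes, without the intensity trend, with array signal (2.44 ± 0.26) or slide (2.29 ± 0.26) as a covariate (with slide, 1 other gene passed), and without either PSX706, either PSX626, PS432 10 mM, any DMSO array, or the PS432 25 mM array at 4, 8 or 48 h.

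PSX626 was compared with DMSO in the same way (n = 2 arrays), and 238 genes at 25 mM and 293 at 50 mM differed by at least 2-fold on single arrays. The directions were opposite, with 188 higher and 50 lower at 25 mM and 5 higher and 288 lower at 50 mM. Under quantile scaling the counts were 240 and 191. Heat shock genes had a median of 0.12, with HSPH1, a chaperone gene, at 0.37 ± 0.18, although against DMSO at 24 h alone the list was -0.06 and 0.08 and HSPH1 0.02 and 0.20 at 25 and 50 mM. Metallothioneins, which bind zinc and copper, had a median of -0.29, with MT2A at -0.44 ± 0.19. These were the 2 lists that passed camera (adjusted p = 0.00775 and 0.0024, and adjusted p = 0.895 with an estimated correlation for both), with 0 members adjusted over the list alone. STXBP2, a gene of vesicle release, was -0.73 ± 0.19 and FGF11 -1.12 ± 0.28, each with an adjusted p of 1. NF-kappaB targets had a median of 0.02 at both 25 and 50 mM, and ATF4 genes 0.07 and 0.17 on these single arrays (percentiles 98.2 and 100). In the fit the ATF4 median was -0.08 with 17 of 25 negative (camera adjusted p = 0.237, and adjusted p = 0.895 with an estimated correlation). Limma called 0 genes (389 at an unadjusted p under 0.05, below the 1078 expected by chance), and 2 without the 50 mM array. The 50 mM array was brighter than the 25 mM array, and 926 of the 937 genes that differed 2-fold between them were lower at 50 mM. Under quantile scaling 550 genes differed 2-fold between them.

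PSX146 at 25 mM (n = 1 array) differed from DMSO in cell division genes more than in any other list tested, by the size of the list median. Its own variation cannot be estimated from 1 array, so every p-value and call for it rests on the spread of the other arms. DNA replication genes had a median of -1.91 and mitosis genes of -1.59, with 29 of 29 and 25 of 25 members called adjusted over the list alone (camera adjusted p = 1.84e-18 and 3.08e-22, and adjusted p = 0.480 with an estimated correlation for both). CCNB1, the cyclin of mitotic entry, was -1.44 ± 0.27, and TSC22D3, a leucine zipper gene induced by glucocorticoids, 2.37 ± 0.38. ATF4 genes had a median of 1.20 (16 of 25 adjusted over the list alone; camera adjusted p = 9.96e-12, and adjusted p = 0.480 with an estimated correlation). ASNS was 1.68 ± 0.32. Heat shock genes had a median of -0.53 (7 of 20 adjusted over the list alone; camera adjusted p = 1.35e-08, and adjusted p = 0.480 with an estimated correlation). HSPA1A was -2.28 ± 0.48. NF-kappaB targets had a median of 1.48 and p53 targets of 0.62, with 4 members of each adjusted over the list alone (camera adjusted p = 1.65e-05 for both, and adjusted p = 0.520 with an estimated correlation for both).

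Immediate early genes (1.01; 5 adjusted over the list alone), ERK output (0.83; 3), YAP/TAZ targets (0.74; 2), metallothioneins (0.62; 5), the BCL2 family (0.43; 5), mesenchymal genes (0.41; 0), the unfolded protein response (0.39; 0) and ribosomal proteins (0.27; 0) were also higher by camera, between adjusted p = 0.480 and 0.677 with an estimated correlation. Limma called 0 genes (3570 at an unadjusted p under 0.05; lowest adjusted p = 0.251). It called 4 with normexp and quantile normalization, 2 without PS432 50 mM, 1 without the filter on dim probes and 1 without the intensity trend.

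Against PS432 at the matched dose of 25 mM, with 1 array each and no test, PSX146 had lower DNA replication and mitosis medians (-0.89 and -0.75, percentile 0 for both) and higher unfolded protein response, cholesterol and metallothionein medians (0.79, 0.65 and 0.57, percentile 100 for each). NF-kappaB targets and ATF4 genes differed by 0.09 and 0.07 (percentiles 82.8 and 78.1). HK2 was higher by 2.14 and MMP1 by 2.61, and CLDN2 was -2.96. In all, 425 genes differed 2-fold from PS432, 1533 from PSX706 and 2892 from PSX626 at 25 mM.

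**Figure D2:**
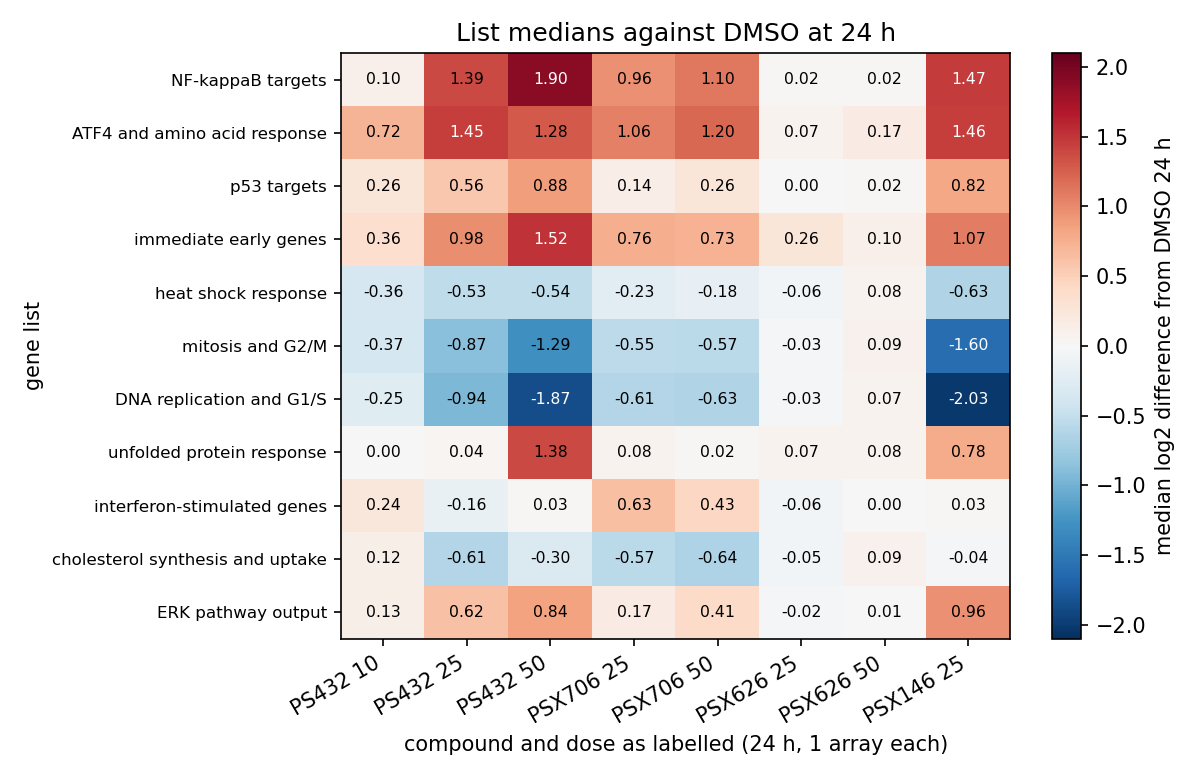
Median log2 difference from DMSO at 24 h for gene lists with each compound and dose, 1 array per condition. The ATF4 list lies between 0.07 and 0.17 with PSX626 and between 0.72 and 1.46 with the other compounds.

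**Figure D3:**
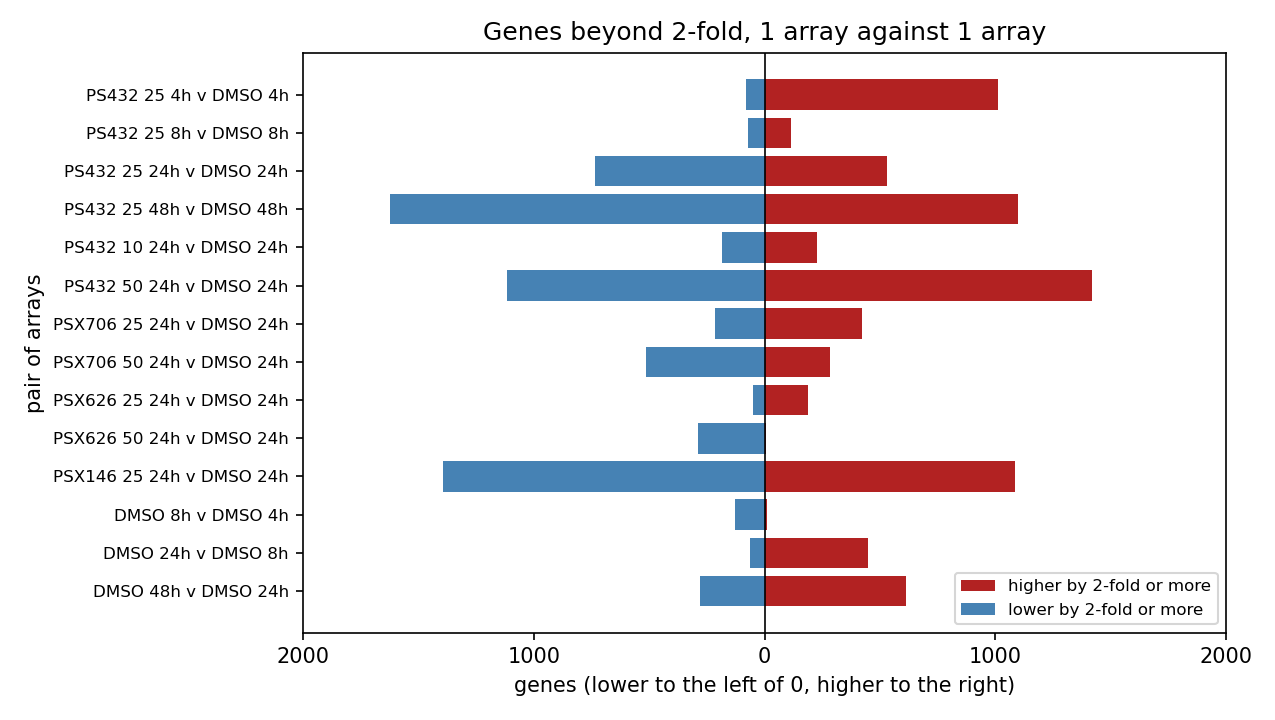
Number of genes at least 2-fold higher or lower in each pair of single arrays, with pairs of DMSO arrays for scale. PSX146 25 mM and PS432 50 mM differ from DMSO in 2480 and 2539 genes and PSX626 in 238 and 293.

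PSX706 was compared with PS432 at matched doses (25 and 50 mM, 24 h, n = 2 arrays each). Interferon-stimulated genes were higher with PSX706, by a list mean of 1.05 ± 0.12 (95% interval 0.77 to 1.32), with 15 of 22 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.72e-11, and adjusted p = 0.411 with an estimated correlation). IFIT1, which binds viral RNA, differed by 3.98 ± 0.28 and OASL by 2.30 ± 0.25, both with an adjusted p of 0.192. Against DMSO at 25 and 50 mM, IFIT1 stood at 0.82 and 0.59 with PSX706 and at -3.68 and -2.87 with PS432. DNA replication genes were higher with PSX706 than with PS432, with 29 of 29 positive and a list mean of 0.84 ± 0.23 (0.30 to 1.37; 0 adjusted over the list alone; camera adjusted p = 3.89e-16, and adjusted p = 0.499 with an estimated correlation). p53 targets had a list mean of -0.56 ± 0.11 (13 of 22 adjusted over the list alone; camera adjusted p = 7.26e-13, and adjusted p = 0.411 with an estimated correlation). CDKN1A was -1.21 ± 0.14. ERK output had a list mean of -0.53 ± 0.10 (7 of 14 adjusted over the list alone; camera adjusted p = 1.05e-05, and adjusted p = 0.411 with an estimated correlation). FOSL1 was -1.81 ± 0.25.

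HSPA1A was 1.49 ± 0.12 between the compounds, and heat shock and mitosis genes had medians of 0.34 and 0.53 (4 and 12 adjusted over the list alone; camera adjusted p = 3.22e-09 and 1.68e-12, and adjusted p = 0.411 and 0.428 with an estimated correlation). Genes linked to PKC-iota in cancer had a median of 0.28 (2 of 7 adjusted over the list alone; camera adjusted p = 0.0385, and adjusted p = 0.428 with an estimated correlation). Their member SOX2, a stemness factor gene, was 1.60 ± 0.34. The ATF4 list's mean did not separate these compounds by limma (-0.17, 95% interval -0.43 to 0.09, adjusted p = 0.270), although camera gave 0.011 and adjusted p = 0.528 with an estimated correlation. Medians lower with PSX706 were those of the unfolded protein response (-0.68; 0 adjusted over the list alone), NF-kappaB targets (-0.53; 6), metallothioneins (-0.42; 7), immediate early genes (-0.42; 2), the BCL2 family (-0.38; 5), ribosomal proteins (-0.22; 0) and YAP/TAZ targets (-0.21; 2), all by camera and none below adjusted p = 0.411 with an estimated correlation. Limma called 0 genes (2619 at an unadjusted p under 0.05). In the 16-array fit 1 was called, with array signal as a covariate 468, and 7362 on slide 2 alone, a fit without PS432 25 mM and with 1 residual degree of freedom.

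PSX626 and PS432 differed at matched doses (n = 2 arrays each) in 2168 genes, 1043 higher and 1125 lower with PSX626 (limma). NIBAN1 was lower with PSX626 by a log2 value of -5.18 ± 0.25 (95% interval -5.82 to -4.53, and adjusted p = 0.0155) and BEX2 by -4.72 ± 0.31 (0.0155). SESN2 was -3.26 ± 0.14 (0.0155), and ICAM1, an adhesion molecule induced by NF-kappaB, -3.72 ± 0.24 (0.0155). CCNE2, a cyclin of S phase entry, was 2.39 ± 0.36 (0.028), and CLDN2 4.26 ± 0.83 (0.0439). PTX3, RPS6KA2 and CSF2 were at least 26.5, 17 and 12.7-fold lower with PSX626, and PRR15L and SLC26A9 at least 14.6 and 10.6-fold higher.

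Of the ATF4 list 21 of 25 were lower with PSX626 (22 adjusted over the list alone), with a list mean of -1.40 ± 0.11 (95% interval -1.65 to -1.14; camera adjusted p = 4.97e-14, and adjusted p = 0.411 with an estimated correlation). DDIT3 was -3.06 ± 0.32 and ATF3 -2.89 ± 0.33. NF-kappaB targets were lower in 13 of 22 cases and higher in 1 (19 and 1 adjusted over the list alone; list mean -1.72 ± 0.20, -2.18 to -1.25; camera adjusted p = 8.6e-11, and adjusted p = 0.411 with an estimated correlation). CXCL8, the interleukin-8 gene, was at least 13.8-fold lower. DNA replication genes were higher in 20 of 29 and mitosis genes in 19 of 25 (29 and 24 adjusted over the list alone), with list means of 1.48 ± 0.23 and 1.07 ± 0.14 (camera adjusted p = 1.62e-15 and 5.95e-15, and adjusted p = 0.411 with an estimated correlation for both). p53 targets were lower in 12 of 22 (17 lower and 1 higher adjusted over the list alone) and the BCL2 family in 8 of 15 (10 and 1), with CDKN1A at -2.20 ± 0.14 and BBC3 at -1.93 ± 0.21 (camera adjusted p = 2.03e-09 and 7.46e-05, and adjusted p = 0.411 with an estimated correlation for both). Cholesterol genes were higher in 8 of 25 (10 adjusted over the list alone; camera adjusted p = 9.3e-06, and adjusted p = 0.411 with an estimated correlation).

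Heat shock genes were higher in 6 of 20 (18 adjusted over the list alone), with HSPA1A at 2.16 ± 0.12. Fatty acid genes were higher in 3 of 14 (6 adjusted over the list alone), with the desaturase gene FADS2 at 1.57 ± 0.12. ERK output was lower in 7 of 14 and higher in 1 (9 and 1 adjusted over the list alone), with FOSL1 at -2.81 ± 0.25. Immediate early genes were lower in 5 of 14 and higher in 1 (12 and 1), with JUN at -2.22 ± 0.13 and FOS at 1.89 ± 0.23. YAP/TAZ targets were lower in 6 of 20 and higher in 1 (8 and 1 adjusted over the list alone), metallothioneins lower in 1 of 8 (5), the unfolded protein response in 1 of 19 (1) and ribosomal proteins in 0 of 22 (0). Camera's adjusted p for these 8 lists lay between 2.48e-09 and 0.0067, and between adjusted p = 0.411 and 0.636 with an estimated correlation. The 6-array calls were 0 in the 16-array fit (2713 at an unadjusted p under 0.05) and without the intensity trend (5539), 5342 with array signal as a covariate, and 10372 on slide 2 alone.

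PSX626 and PSX706 were compared in the same way (n = 2 arrays each). ATF4 genes were lower with PSX626 by a list mean of -1.22 ± 0.11 (95% interval -1.48 to -0.97), with 22 of 25 passing adjusted over the list alone (camera adjusted p = 6.4e-26, and adjusted p = 0.302 with an estimated correlation). AXIN2 and RNF43 were 3.08 ± 0.22 and 2.62 ± 0.21 for PSX626 minus PSX706, and TRIB3, a pseudokinase gene of the ATF4 list, was -1.83 ± 0.10 (adjusted p = 0.103 for each). NF-kappaB targets had a list mean of -1.20 ± 0.20 (14 lower and 1 higher adjusted over the list alone) and interferon-stimulated genes of -0.72 ± 0.12 (9 of 22), with OASL at -2.74 ± 0.25 (camera adjusted p = 6.19e-16 and 2.14e-08, and adjusted p = 0.302 with an estimated correlation for both). Cholesterol genes were higher with PSX626, with 25 of 25 positive and a list mean of 0.66 ± 0.13 (15 adjusted over the list alone; camera adjusted p = 2.95e-15, and adjusted p = 0.302 with an estimated correlation). Mitosis genes had a list mean of 0.57 ± 0.14 (16 of 25 adjusted over the list alone) and replication genes of 0.64 ± 0.23 (0), with adjusted p = 0.302 and 0.459 with an estimated correlation.

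Fatty acid genes (0.41; 3 adjusted over the list alone), AhR targets (0.35; 0), heat shock (0.25; 0) and glycolysis genes (0.13; 0) were higher by camera with PSX626. Immediate early genes (-0.71; 4 lower and 1 higher), ERK output (-0.38; 4 and 1), YAP/TAZ targets (-0.29; 5), the BCL2 family (-0.25; 5), lysosome and autophagy genes (-0.24; 3 lower and 1 higher), p53 targets (-0.16; 5) and mesenchymal genes (-0.16; 1) were lower, none below adjusted p = 0.302 with an estimated correlation. Limma called 0 genes (2615 at an unadjusted p under 0.05). It called 1 in the 16-array fit, 3 with quantile scaling, 5 with normexp and quantile normalization, 74 without the filter on dim probes, 2084 with array signal as a covariate and 5112 on slide 2 alone.

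**Figure D4:**
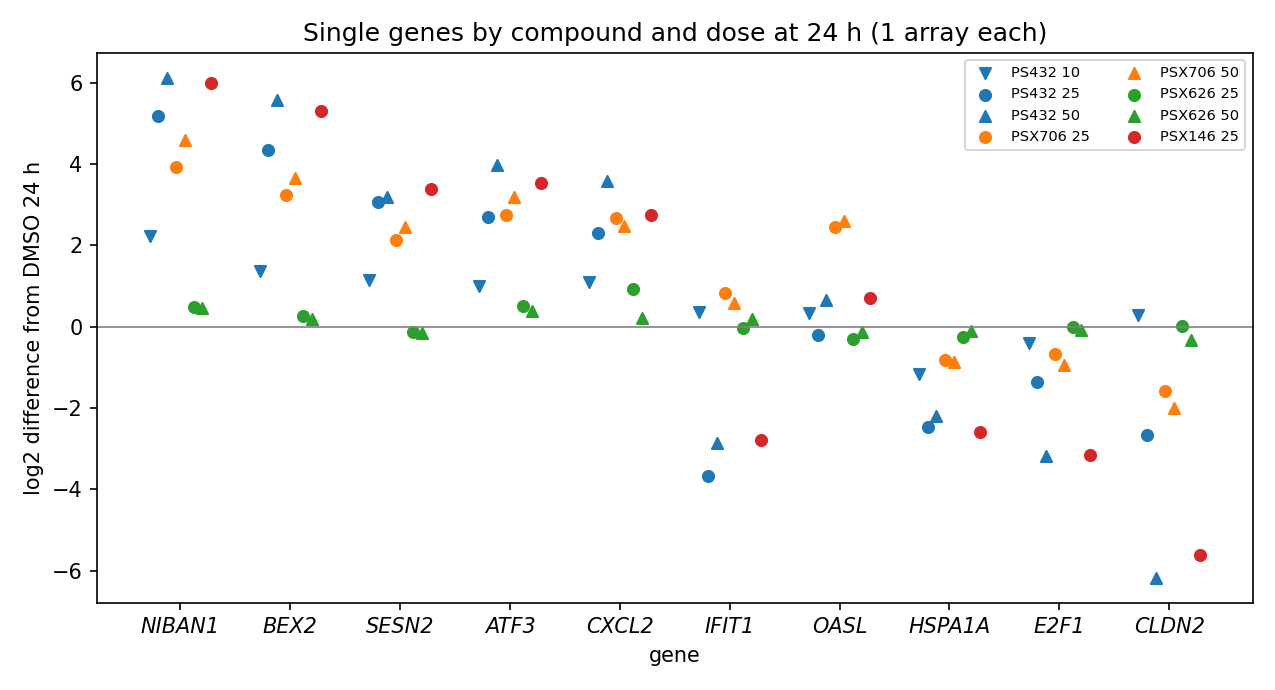
Log2 difference from DMSO at 24 h of named genes with each compound and dose, 1 array per condition. NIBAN1 lies at 5.18 with PS432 25 mM, 3.93 with PSX706 25 mM, 0.48 with PSX626 25 mM and 5.99 with PSX146 25 mM.

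Some lists did not pass camera in any comparison: the aPKC and polarity complex, hypoxia, epithelial junction and keratin genes, and leukocyte markers, whose medians with PS432 25 mM over 4 times were 0.01, 0.20, 0.04 and -0.15 (camera adjusted p = 0.671, 0.138, 0.972 and 0.360). By limma on the list mean, the 5 leukocyte markers passed in the time trend (-0.52, adjusted p = 0.00856), with dose (-0.16, 0.0207), and for PSX706 and PSX626 against PS432 (0.51, 0.0254, and 0.60, 0.00419). None of the 4 lists passed with an estimated correlation. In that comparison the medians of oxidative phosphorylation, lysosome, ribosome biogenesis, interferon-stimulated, fatty acid, AhR, metallothionein, unfolded protein response and alveolar genes lay between -0.07 and 0.08. Only 3 fibroblast and 3 endothelial marker genes were measured, too few for a test.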

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

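The fits with array signal as a covariate, and the counting of splits that give the same fit only once, were chosen after the results were seen, and the other tests of this part were set before.

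The PS432 25 mM effect differed between times in 3107 genes by the interaction of treatment and time. It also differed in 12 of 29 lists by camera, of which 0 passed with an estimated correlation (lowest adjusted p = 0.585 with an estimated correlation). PSX626 differed from PS432 at matched doses in 2168 genes and 15 lists, PSX706 from PS432 in 15 lists, and PSX626 from PSX706 in 17. With an estimated correlation 0 lists passed in these 3 comparisons (lowest adjusted p = 0.411, 0.411 and 0.302 with an estimated correlation).

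Some pairs of arrays differed almost wholly in 1 direction, such as PS432 25 mM over DMSO at 4 h (1013 genes 2-fold higher, 80 lower) and PSX626 50 over 25 mM (11 higher, 926 lower). An early PS432 response that lasted to 8 h was not seen in the 1013 genes as a set, since their median difference was 0.0012 at 8 h (quartiles -0.205 and 0.226). A response at 4 h that ended by 8 h would give the same value and was not excluded. Single genes did differ by at least 2-fold at both 4 and 8 h, such as DDIT3 (1.70 and 2.51) and CXCL2 (1.74 and 1.76). The level of array signal may account for the pattern: the dim minus bright differences of those pairs, which share no array, had r = 0.711 across 17726 genes (genes are not independent replicates), against -0.0794 with the 8 h pair of like brightness. That the effect is limited to dim genes cannot be told apart from a general one, with 84% of the 926 genes below the median expression, between the bounds set for either outcome. A difference in labelling or RNA amount behind the array signal was not tested.

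The time and dose trends with PS432 (3107 and 2221 genes) were weighed against array signal, and the time trend also against chance. Of the time calls 14.7% and of the dose calls 6.3% moved the way array signal would move them. This count cannot exclude array signal, as only 116 genes were lower on the dim arrays of both PSX706 and PSX626, against 2290 higher. Few time rises or dose falls could therefore count. Of the calls that could, 24.4% of the time falls and 12.3% of the dose rises were genes higher on the dim arrays, against 10.6% of all genes. The time slopes had r = -0.425 and -0.513 with the PSX626 and PSX706 pairs of dim minus bright arrays, and the dose slopes 0.167 and 0.0277. With array signal as a covariate, 98.3% of the time calls kept their sign, their median slope went from 0.408 to 0.396 and its SE from 0.079 to 0.150 with 1 residual degree of freedom, and 710 were called; for dose, which was nearly confounded with array signal (r = -0.851 over 4 arrays), 100% kept their sign, the slope went from 0.298 to 0.312, and 0 were called, as the SE went from 0.0496 to 0.101 with 1 residual degree of freedom. For the time trend 1 of 20 distinct splits of the 8 arrays, the real one, gave 3107 genes and the highest other 2738 (1800 among the 8 splits that part the 2 arrays of every time, as the real one does), and 20 splits, or 8, are too few for a share under 0.05. The split with 2738 parts only the arrays at 24 and 48 h. Its tested term then rests on the PS432 minus DMSO differences at those times, so it is not free of treatment. The split with 1800 is the real one with the 2 arrays of 4 h exchanged, so it is not free of treatment either. A compound effect on these genes is a hypothesis that stays open, as are array signal and the cultures, which were not tested. Slide stays open for the time calls beyond the 951 also called on slide 1 alone (1261 without 48 h), and for the dose calls. With slide as a covariate in the fit of all 16 arrays (5497), 2045 dose genes were also called. That fit assumes the same straight dose slope at every time, which the time trend speaks against, so it cannot set slide aside.

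For PS432 25 mM over 4 times, 2 of 20 distinct splits gave as many genes at an unadjusted p under 0.05 as the real 3687 (highest other 6523), and 20 splits are too few for a share under 0.05. The other split, which parts the arrays of 2 times only, called 3115 genes against 0, which points to a structure of the samples, and among the 8 splits that part them at every time the real one was highest (next 3045). For PS432 over all doses, chance was not excluded, with 9 of 69 distinct drawn splits reaching the real 3826 (highest other 7646).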

How the results depend on the processing

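Alternatives with array signal as a covariate, with limma on list means, and list tests without 4 h or with quantile scaling were chosen after seeing the data. Over all alternatives, 0 values of named genes called in the main fit changed sign. Changes of sign in genes not called there were not counted apart. In the comparisons that called 0 genes, the values that moved by more than the SE ranged from 6 of 1056 for PSX146 to 97 of 599 for culture time. Of the alternative gene counts, those within 1.5 times numbered 10 of 15 for PS432 25 mM over 4 times, 6 of 12 for its time trend, 12 of 14 for culture time, 6 of 13 for dose, 8 of 24 for PSX706, 23 of 24 for PSX626, 19 of 23 for PSX146, 13 of 24 for PS432 over all doses, and 6, 5 and 3 of 9 for PSX706 against PS432, PSX626 against PS432 and PSX626 against PSX706. The cause was not tested for the changes that follow, except where fewer arrays or residual degrees of freedom are named.

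Without the intensity trend in eBayes, 0 genes were called for the time trend, dose, PSX706, PS432 over all doses and PSX626 against PS432, and 1 for PSX146. Without the filter on dim probes the counts were 1717 for the time trend, 3478 for dose, 0 for PSX706, 1 for PSX146 and 74 for PSX626 against PSX706. With array signal they were 605 for PS432 over 4 times, 710 for the time trend, 0 for dose, 0 for PSX706, 12 for PS432 over all doses, and 468, 5342 and 2084 for PSX706 against PS432, PSX626 against PS432 and PSX626 against PSX706. On slide 2 alone, with 5 arrays and 1 residual degree of freedom, these 3 gave 7362, 10372 and 5112, and in the 16-array fit 1, 0 and 1. Slide as a covariate in the fit of all 16 arrays (for PS432 over 4 times and dose, more arrays and residual degrees of freedom) gave 30 for PS432 over 4 times, 5497 for dose and 2 for PS432 over all doses, and arrays sharing a slide 6 for PS432 over 4 times. The authors' table of 1403 genes gave 12 for PS432 over 4 times and 799 for the time trend. Log dose gave 0 for dose, the 24 h arrays 0 for PSX706 and 0 for PS432, and DMSO arrays only 649 for culture time. Normexp with quantile normalization gave 4 for PSX146 and 5 for PSX626 against PSX706, and quantile scaling 3 for the latter and 191 genes beyond 2-fold for PSX626 50 mM against DMSO.

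Leaving out 1 array or time at a time gave 0 to 6 for PS432 over 4 times (6 without 48 h), 1261 to 3065 for the time trend (1261 without 48 h, 1643 without 24 h), 0 to 649 for culture time (649 without the untreated array), 0 to 2320 for dose (0 without DMSO, 2 without 50 mM), 0 to 1 for PSX706, 0 to 2 for PSX626 (2 without its 50 mM array), 0 to 2 for PSX146 (2 without PS432 50 mM), and 0 to 727 for PS432 over all doses (727 without 10 mM, 9 without either 48 h array). Where an arm kept 1 array, it was assumed to vary like the others.

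With an estimated correlation 0 lists passed in each of the 11 comparisons. Limma on list means passed 4 for PS432 over 4 times, 3 for culture time, 9 for dose, 0 for PSX706, 0 for PSX626, 3 for PSX146, 5 for PS432 over all doses and 11 for PSX626 against PSX706. With array signal 1 list passed for PSX626. Beyond 1.5-fold and beyond 3-fold, PS432 25 mM differed from DMSO in 3054 and 184 genes at 4 h, 1048 and 38 at 8 h, 3683 and 342 at 24 h and 6414 and 1002 at 48 h, PS432 10 mM in 1776 and 64, PS432 50 mM in 5900 and 875, PSX706 in 2675 and 119 at 25 mM and 3043 and 165 at 50 mM, PSX626 in 1363 and 31 at 25 mM and 1179 and 64 at 50 mM, and PSX146 in 5711 and 911. PSX146 25 mM differed in 1817 and 83 genes from PS432, 4535 and 431 from PSX706 and 6557 and 1020 from PSX626. Not run were the authors' table for dose and for the other compounds, whose arrays it lacks, and PSX146 without its only array. Genes not well above background in an arm limit its folds to bounds.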

Other observations

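The mitochondria-encoded genes and the test of array signal on the interferon genes, like the test of slide, were chosen after their results were seen, and the count of interferon members was set before.

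All 13 protein-coding genes of the mitochondrial genome were on the array, detected on all 16 arrays, and most were lower with PS432 and PSX146. These genes code for subunits of the respiratory chain and ATP synthase, and 12 of them are read from the heavy strand, while ND6 is read from the light strand. Against DMSO the 12 had a median of -2.54 with PSX146 (from -4.76 to -1.07, all 12 lower by at least 2-fold), -1.84 with PS432 25 mM at 48 h (12 of 12 negative), and -0.36, -0.72 and -1.47 with PS432 10, 25 and 50 mM at 24 h. ND6 was 1.15 with PSX146, 0.20 with PS432 at 48 h and 0.90 with PS432 50 mM, but -0.85 and -0.29 with PS432 10 and 25 mM at 24 h and -1.14 with PS432 at 8 h, where the median of the 12 was -0.27. In limma 12 of the 13 fell per doubling of time with PS432 and 9 fell with PS432 dose, ND6 not being among them, and 8 were higher with PSX626 than with PS432. COX2, here the mitochondrial gene of cytochrome c oxidase subunit 2, fell by 0.97 ± 0.12 per doubling (adjusted p = 0.00402) and by 0.65 ± 0.04 per 10 mM (0.00961), and was 2.36 ± 0.19 for PSX626 minus PS432 (0.0155).

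Other values of these 12 genes went with array signal: the median was 0.67 with PS432 at 4 h, where the PS432 array was dim, and with 25 and 50 mM it was 0.14 and -0.79 for PSX706 and 0.40 and -0.50 for PSX626, where the 50 mM arrays were brighter. Under quantile scaling the medians were -2.50 with PSX146, -1.89 with PS432 at 48 h and -1.52 with PS432 50 mM. Between DMSO arrays the median was 0.66 for 24 minus 8 h and -0.11 for 48 minus 24 h.

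Interferon-stimulated genes were higher with PSX706 than with DMSO, PS432 or PSX626, among them MX1 (2.05 and 1.57 against DMSO at 25 and 50 mM), IFIT2 (1.53 and 1.68) and ISG15 (0.98 and 0.92). The list passed camera in these 3 comparisons but had adjusted p = 0.0593, 0.411 and 0.302 with an estimated correlation, and against DMSO its mean did not pass limma (adjusted p = 0.0899). Slide as the cause was excluded, since the PSX626 arrays of the same slide differed from DMSO at 24 h by a list mean of -0.00871. Array signal did not move the list between PSX626 25 and 50 mM (difference 0.0154). That pair cannot exclude array signal for PSX706, where some members were higher on the dimmer 25 mM array than at 50 mM and others were not. The call of OASL ended with either slide or array signal as a covariate. It was 2.45 ± 0.26 before, 2.44 ± 0.26 with array signal and 2.29 ± 0.26 with slide (limma adjusted p = 0.0377, 0.108 and 0.0742), with 7, 6 and 6 residual degrees of freedom. Whether the pattern belongs to the list or to a few members cannot be told apart, with 8 of 22 members at least 1.5-fold higher at both doses, between the bounds set for either outcome, and BST2 at 1.19 and -0.74. An effect of PSX706 on interferon signalling may be a candidate explanation, but with 1 array per dose a difference between cultures stays open. Array signal also stays open for some members.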
